A study of Rattus norvegicus with 16 samples.

How the data were processed

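RNA was sequenced from 16 rat brain libraries, 4 from each combination of sex and genotype, all from animals 8 months old. The genotypes were wild type and Pink1-/-, a line in which the gene for the mitochondrial kinase PINK1 is disrupted. The labels give the tissue as brain, and the title of the series names the nucleus ambiguus, the medullary cell group whose motor neurons serve the larynx, pharynx and soft palate. Per the labels' protocols, total RNA was extracted from frozen dissected tissue with a kit for fatty and fibrous samples, and sequencing libraries were made with an Illumina TruSeq kit. The labels do not say whether that preparation kept strand. The aligner, genome build and annotation are not given in the sources used here.

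The deposited count tables, 1 per sex, hold estimated counts per gene for 32754 Ensembl rat identifiers. RSEM, with no version stated, and edgeR 3.9 are named in the submitters' processing notes. The deposited estimated counts were already whole numbers, their totals differed between libraries, and they were used without scaling or further rounding. RSEM divides reads between near-identical sequences, so values of multicopy genes and pseudogenes are uncertain. The authors also deposited 1 comparison table per sex. Per the file headers, it gives the log2 fold change of Pink1-/- over wild type, the mean log2 CPM (counts scaled to library size), a likelihood ratio score, a p-value and a false discovery rate. Library columns were matched to the labels through the animal numbers in the titles, which differ between all 16 libraries, so the libraries are taken as separate animals. No per-sample column was left unused (0 columns).

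Males and females were tested separately, because the deposited tables are split by sex and the libraries of each sex resemble a processing run of their own. Genes were kept with the filterByExpr defaults of edgeR (minimum count 10, minimum total 15), scaled by trimmed mean of M-values (TMM) and tested with the quasi-likelihood functions of edgeR 4.0.16 in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± standard deviation (SD) over n = 4 libraries. Log2 CPM values, used for correlations, list scores and principal components, carry a prior count of 2. A difference between the sexes was tested as the interaction of genotype and sex over all 16 libraries. Single measures per library were compared with exact 2-sided permutation tests, in which 4 libraries against 4 cannot give a p under 0.0286.

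A set of 36 gene lists was fixed before the data were examined, along with the tests, the alternatives and the rule for named genes. Of their 887 members, 866 were matched to an identifier, 7 of them through a synonym. The list of sex-linked genes was used only to check labels. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over lists. The rule for named genes took Pink1, then the 10 largest rises and 10 largest falls among called genes that had a gene symbol, a mean of at least 1 CPM and no overlap between the groups. It added up to 4 called members of each list with the smallest p, or, where none was called, the 2 members with the smallest unadjusted p as values only. It also added genes called in both sexes, the interaction genes with a symbol, and, where under 5 genes passed in a direction, the next by p as values that did not pass.

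Alternatives fixed in advance were a looser adjusted p of 0.10, relative log expression (RLE) size factors, library totals as the only scaling, no filter on low counts, a minimum mean of 1 CPM, DESeq2 1.42.0, the likelihood ratio test of edgeR, limma-voom with quality weights, 1 surrogate variable from sva 3.50.0, all 16 libraries in 1 fit, and each library left out in turn. Further alternatives were added after seeing the data and are named as such. Other groupings of the libraries were all 35 splits into 4 and 4 within a sex, and 100 draws where both sexes entered. NCBI gene names and gene order on GRCr8 were used only for synonyms and for which genes neighbour each other; 88.9% of the genes tested in males could be placed.

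The fits were tested on a single simulated data set per design, with counts drawn gene by gene from the means and library sizes of these libraries. Each fold change was given to 49 or 50 genes. Variation shared between genes was not simulated, so the shares called do not compare the power of the real male and female data. In the male design (13589 genes), 4% of genes changed 1.25-fold were called, 48% at 1.5-fold, 79.6% at 2-fold and 96% at 4-fold. In the female design (15105 genes) the shares were 2%, 58%, 84% and 98%, and for the interaction (14904 genes) 0%, 12%, 58% and 88%. Total counts per library ran from 10959412 to 13691846 in males and from 13875621 to 26570195 in females.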

Results

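The data are gene-level RNA counts from the brains of Pink1-/- and wild-type rats of both sexes at 8 months of age, taken for the nucleus ambiguus according to the title of the series. Each of the 4 groups (male wild type, male Pink1-/-, female wild type, female Pink1-/-) holds 4 libraries, named here by the animal number in the labels. Total counts were 12638731 ± 774795 (SD, n = 4) in male wild type and 12929552 ± 1313854 in male Pink1-/-. They were 21753198 ± 4115903 in female wild type and 20027560 ± 4134869 in female Pink1-/-. Between 17918 and 18994 identifiers had a count in a library. Replicates of a group differed by more than counting noise in all 24 pairs, so no library appears to be deposited more than once, with correlations of log2 CPM across genes between 0.970 and 0.985. That they are separate animals rests on the animal numbers in the labels. All 16 libraries matched the sex in their labels by the Y-linked genes Eif2s3y (37.0 to 53.8 CPM in males, at most 0.346 CPM in females) and Kdm5d (30.6 to 45.7 CPM in males, at most 0.519 CPM in females). The other Y-linked genes examined had few counts and did not separate the sexes: Ddx3y had 1 to 11 counts in males and 0 to 27 in females (27 each in wild-type 64 and 111), and Usp9y had at most 1 count in any library.

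The libraries of each sex had a composition of their own. In males, 2 loci named after a clone of the rat mitochondrial genome took 36.5% to 44.0% of all counts, and in females 1.77% to 11.9%. The small cytoplasmic 7SL RNA of the signal recognition particle took 0.282% to 4.28% of counts in males and 9.14% to 15.8% in females. Sex and library processing therefore cannot be told apart, and levels are compared here within a sex only. The first principal component held 38.1% of the variance among male libraries and separated the genotypes (exact permutation p = 0.0286, the smallest possible with 4 against 4). Its ends were Pink1-/- 17 (42.7) and wild-type 23 (-38.0), which also had the highest and lowest 7SL shares of the males (4.28% and 0.282%). The male component therefore cannot be read as genotype alone. In females the first component held 22.7% and did not separate the genotypes (exact permutation p = 0.943).

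Pink1 encodes the mitochondrial kinase that marks damaged mitochondria for removal, and it was the gene with the smallest p in males. Male wild-type libraries had 69.6 ± 6.04 CPM of Pink1 (SD, n = 4) and male Pink1-/- libraries 1.88 ± 0.347 CPM, a 36.7-fold lower level (log2 fold change -5.20, SE 0.13, edgeR adjusted p = 2.0e-10). Female wild-type libraries had 128 ± 9.41 CPM and female Pink1-/- libraries 7.06 ± 3.23 CPM, a 17.9-fold lower level (log2 fold change -4.16, SE 0.25, edgeR adjusted p = 5.6e-05). In counts, wild-type males ran from 779 to 1030 and Pink1-/- males from 21 to 34. Wild-type females ran from 2139 to 3287 and Pink1-/- females from 68 to 267. All libraries carried the level their genotype label calls for (exact permutation p = 0.0286 in each sex, the smallest possible).

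**Figure D1:**
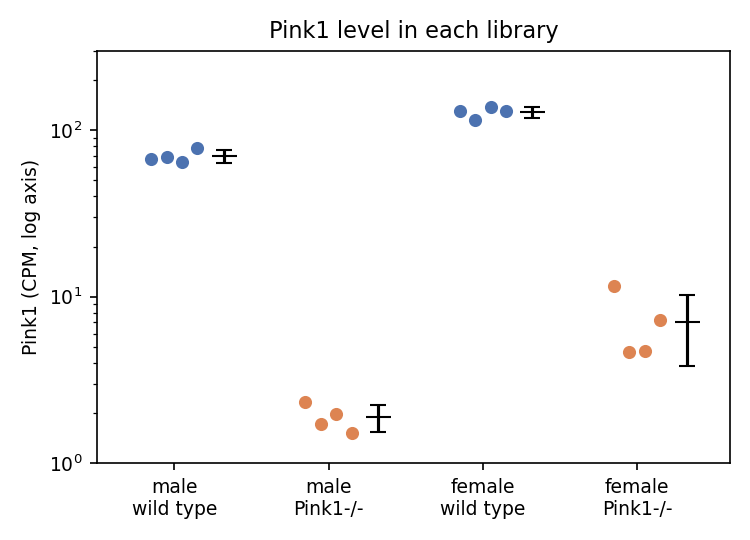
Pink1 in each library, in CPM on a log axis, for the 4 groups; points are libraries and black bars the mean ± SD (n = 4). Pink1-/- libraries averaged 1.88 CPM in males and 7.06 CPM in females, below every wild-type library of the same sex.

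The male comparison asks which transcripts differ between Pink1-/- and wild-type males. Male Pink1-/- brains had 149 genes that rose and 168 that fell, and 78 of these 317 changed more than 2-fold (46 up, 32 down). Among genes with a symbol and a mean of at least 1 CPM, the steepest rises were in Mocos, which activates molybdenum cofactor enzymes, Rpl30, a protein of the large ribosomal subunit, and Jhy, a gene needed for the cilia of ependymal cells. The steepest falls among them besides Pink1 were in Polq, a DNA polymerase of end joining, Slc39a12, a zinc importer of the brain, Pex11a, a peroxisome division factor, and Lilrb3, an inhibitory receptor of myeloid cells. The cystine importer Slc7a11 and the serine synthesis enzyme Psat1 also fell.

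Mocos rose from 0.239 ± 0.0146 to 2.0 ± 0.405 CPM (n = 4 per group), with a log2 fold change of 3.02 (SE 0.31, edgeR adjusted p = 0.00030). Rpl30 rose from 4.40 ± 0.678 to 19.8 ± 4.42 CPM (log2 fold change 2.16, edgeR adjusted p = 7.0e-05). Its wild-type level lay far under the 83 CPM of Rpl23a, and ribosomal protein genes have many near-identical copies between which reads can be split. Jhy rose from 5.82 ± 0.155 to 25.1 ± 3.02 CPM (log2 fold change 2.11, SE 0.11, edgeR adjusted p = 1.6e-06). Other rises were in the acrosomal protein gene Eqtn (2.04), Pbld1 (1.87), the olfactory receptor pseudogene Olr1747-ps (1.80), the tyrosine kinase Fes (1.53), the mitochondrial oxidoreductase Pyroxd2 (1.45), the Cdc42 exchange factor Fgd3 (1.43) and the microtubule-binding Eml1 (1.40), all as log2 fold changes. Their edgeR adjusted p lay between 0.00017 for Eml1 and 0.0387 for Fes.

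Polq fell from 4.58 ± 1.07 to 0.904 ± 0.194 CPM (n = 4 per group), with a log2 fold change of -2.33 (SE 0.24, edgeR adjusted p = 0.00036). Slc39a12 fell from 31.4 ± 9.42 to 6.80 ± 0.931 CPM (log2 fold change -2.20, edgeR adjusted p = 0.00013), and Pex11a from 14 ± 2.52 to 3.11 ± 0.458 CPM (-2.17, edgeR adjusted p = 5.9e-05). Lilrb3 had a log2 fold change of -2.17 and the T cell and macrophage receptor Cd4 of -1.75. The small proteoglycan gene Ogn stood at -1.81, although its symbol belongs to more than 1 identifier. The carbonic anhydrase Car3 (-1.58), Ccdc122 (-1.48), the transfer RNA modifier Dtwd2 (-1.43) and the death receptor Fas (-1.43) completed the 10 largest falls besides Pink1 under the rule for named genes, with edgeR adjusted p of at most 0.0229.

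**Figure D2:**
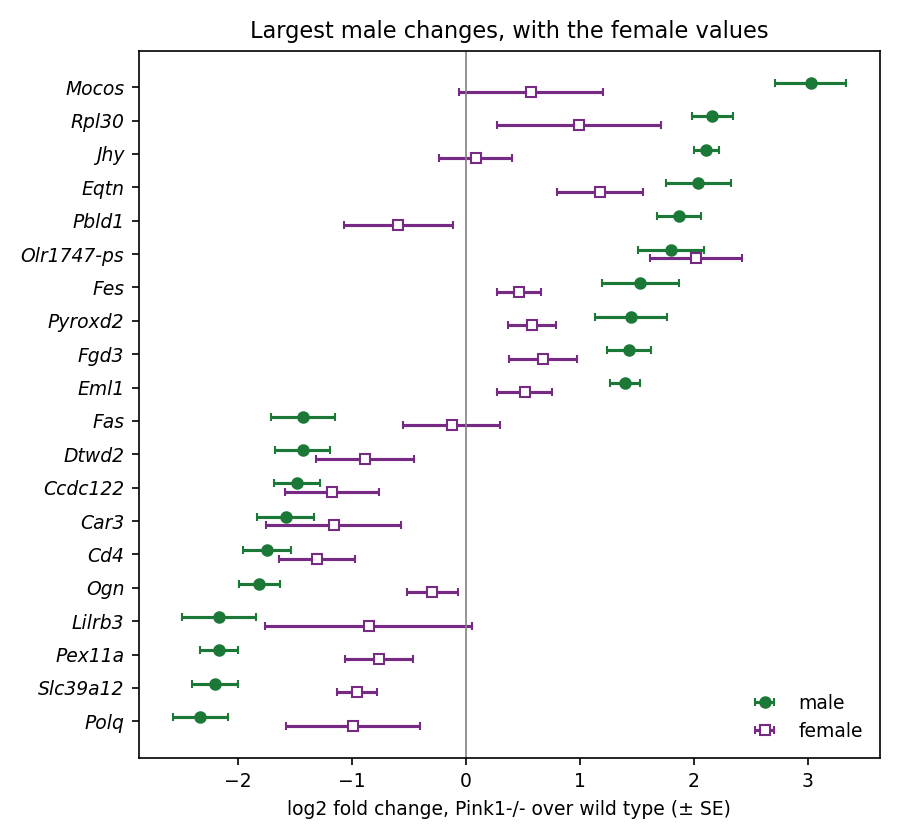
Log2 fold changes of Pink1-/- over wild type (x axis, ± SE) for the 10 largest rises and 10 largest falls called in males, with filled circles for males and open squares for females (n = 4 libraries per group). Pink1 is left out, and only genes with a symbol, a mean of at least 1 CPM and no overlap between the groups were eligible. Of the 20 genes, 19 had the same sign in females, and Pbld1 had the opposite one.

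Of the 317 male calls, 37 were loci without a gene symbol. Among these, 5 identifiers had identical counts in every library, so counting them once leaves 313 calls. The 4 Pink1-/- libraries lay entirely on one side of the 4 wild-type libraries for 313 of the called genes. Over all 13770 genes tested this held for 15.2%, against 2.86% by chance. At an unadjusted p under 0.05, 3613 genes (26.2%) differed, and the common biological coefficient of variation was 0.126. Leaving out 1 library brought the count to between 98 and 217: without wild-type 20, 22, 23 and 24 it was 178, 98, 132 and 188, and without Pink1-/- 17, 18, 19 and 25 it was 185, 127, 217 and 164. Scaling by library totals gave 168 calls and 1 surrogate variable 61, whereas DESeq2 gave 853.

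None of the 34 testable gene lists differed between male genotypes by camera (0 lists), and 4 had an unadjusted p under 0.05. The smallest adjusted p was 0.0751, for the list of PINK1-Parkin mitophagy genes, which holds Pink1 itself, and it was 0.998 for that list without Pink1, a setting chosen after the data were seen. With an estimated correlation 0 lists passed and 1 had an unadjusted p under 0.05, and with fry 0 passed and 4 did. For 14 lists the median, the mean and the test differed in sign, which left those lists without a direction. In 14 lists at least 1 member changed over all genes tested, and in 21 lists at least 1 did when adjusted over the list alone.

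Few members of the energy lists were called in males. Of 35 nuclear complex I genes, 1 rose (Ndufb7, 4.25 ± 0.959 to 8.47 ± 2.55 CPM, log2 fold change 1.0) and 1 fell (Ndufa6, 42.7 ± 3.05 to 30.2 ± 4.57 CPM, -0.50); adjusted over the list alone, 2 rose and 2 fell. Of 38 nuclear genes of complexes II to V, 1 fell, the Rieske protein gene Uqcrfs1 (log2 fold change -0.31, edgeR adjusted p = 0.0489), and 1 did when adjusted over the list alone. All 13 mitochondrially encoded genes had a negative log2 fold change, with a median of -0.21, and 0 passed, also adjusted over the list alone. Mt-nd3 stood at -0.39 (edgeR adjusted p = 0.187) and Mt-cox3 at -0.26 (0.256). The 13 genes took 8.93% ± 0.291 of counts in wild-type males and 7.72% ± 1.23 in Pink1-/- males (exact permutation p = 0.0286, the smallest possible), with Pink1-/- 17 at 5.89% and the other Pink1-/- males at 8.21% to 8.57%, against 8.69% to 9.34% in wild type. In the tricarboxylic acid cycle list 0 of 22 genes passed, with Me3 at -0.49 and Dld at -0.31. In glycolysis 0 of 19 passed, and 1 rose and 1 fell when adjusted over the list alone, with Gpi at 0.33 and Tpi1 at -0.36.

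Among mitophagy genes in males, Pink1 was the only 1 of 30 to pass over all genes, and adjusted over the list alone 1 gene rose and 1 fell. The autophagy receptor Sqstm1 stood at 0.36 (edgeR adjusted p = 0.0532) and the mitochondrial deubiquitinase Usp30 at 0.41 (0.0828). Of 19 genes for familial parkinsonism 0 passed, and 1 rose and 1 fell when adjusted over the list alone, with Chchd2 at 0.54 (0.0523) and Vps35 at -0.33 (0.0792). Of 35 autophagy and lysosome genes, 1 fell, the conjugation factor Atg12 (57.3 ± 6.06 to 40.0 ± 4.77 CPM, log2 fold change -0.52, edgeR adjusted p = 0.0242), while 5 rose and 2 fell when adjusted over the list alone. In the proteasome list 0 of 40 passed and 3 rose adjusted over the list alone, with Psmd3 at 0.53 (0.0577) and Psmb3 at 0.31 (0.0649).

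Of 26 antioxidant genes in males, Slc7a11 alone fell, from 62.1 ± 6.96 to 29.5 ± 4.84 CPM (log2 fold change -1.08, SE 0.12, edgeR adjusted p = 0.00045), with the same count of 1 adjusted over the list alone. Psat1 fell from 122 ± 5.53 to 76.9 ± 11.1 CPM (log2 fold change -0.67, edgeR adjusted p = 0.0039) as the 1 called gene of 26 in the stress response list, where 1 rose and 1 fell adjusted over the list alone. In the heat shock list 0 of 16 passed, and 2 fell adjusted over the list alone, with Chordc1 at -0.35 and Hspa4l at -0.25. Of 72 cytosolic ribosome genes 3 rose, namely Rpl30, Rpl23a (0.35) and Rps10 (0.69), and adjusted over the list alone 5 rose and 2 fell.

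Glial, vascular and meningeal lists held few called members in males. The perivascular macrophage receptor Mrc1 fell (8.38 ± 0.903 to 5.52 ± 0.607 CPM, log2 fold change -0.61) and the microglial purine receptor P2ry12 rose (8.49 ± 1.35 to 12.9 ± 1.44 CPM, 0.59), the only calls among 21 genes, with 1 rise and 2 falls adjusted over the list alone. Of 26 myelin genes, 2 fell, the iron carrier Tf (924 ± 126 to 622 ± 72.9 CPM, -0.57, edgeR adjusted p = 0.0262) and the acetylaspartate hydrolase Aspa (-0.42). Adjusted over the list alone, 3 myelin genes rose and 4 fell. Gpr17, a receptor of maturing oligodendrocyte precursors, rose from 2.29 ± 0.443 to 4.48 ± 0.476 CPM (0.97, edgeR adjusted p = 0.0187), 1 of 10 genes in its list, with 1 rise and 2 falls adjusted over the list alone. Pdgfrb, a pericyte receptor, rose (0.58, edgeR adjusted p = 0.0318), 1 of 20 vascular genes under either adjustment. Ogn was the 1 called gene of 15 in the meninges list and complement C3 (-0.46, edgeR adjusted p = 0.0309) the 1 of 18 in the inflammation list, in each case also adjusted over the list alone. Of 18 astrocyte genes 0 passed, and 1 fell adjusted over the list alone, with Cd44 at -0.74 and Slc1a3 at -0.23.

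Neuronal lists in males held 1 call, the opioid precursor Penk, which rose from 59.9 ± 4.79 to 78.0 ± 6.30 CPM (log2 fold change 0.38, edgeR adjusted p = 0.0369; 1 of 15 neuropeptides, also adjusted over the list alone). Synaptic vesicle genes had 0 of 28 past the threshold and 4 rises adjusted over the list alone (Sv2a 0.30), and inhibitory signalling genes 0 of 24 and 3 rises (Slc32a1 0.52, Gabbr1 0.24). No member passed under either adjustment (0 rises, 0 falls) among 21 cholinergic motor neuron genes (Calcb -1.05, Calca -0.98), 11 catecholamine genes (Maob -0.29, Maoa -0.18), 9 serotonin genes (Htr2c -0.31, Htr3a -0.61) or 25 glutamate genes (Grin2c 0.53, Grin1 0.29). The same held for the lists of interferon response (20 genes; Ifit3 0.87, Stat2 -0.26), antigen presentation (14; Cd74 -0.99, B2m -0.23) and immediate early genes (14; Gadd45b 0.50, Homer1 0.22). It also held for choroid plexus (9; Clic6 -1.0, Kl -0.35), blood (3; Hbb -0.41, Alas2 -0.53), cerebellum (8; Car8 -0.48, Pvalb 0.19) and forebrain position (5; Neurod6 -0.49, Drd2 0.21).

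Named male calls differed in how far they rested on single libraries. Of 42 named calls other than Pink1, 23 held whichever library was left out, among them the rises of Jhy, Rpl30 and Mocos and the falls of Polq, Slc39a12, Pex11a, Slc7a11 and Psat1. The calls of Fes, Pyroxd2, Uqcrfs1, Mrc1 and P2ry12 ended with any 1 library left out, at edgeR adjusted p of up to 0.117, 0.122, 0.140, 0.129 and 0.13. The call of Slc15a2 ended without wild-type 22 (0.0602), that of Fas without wild-type 22 or 23 or Pink1-/- 18 (up to 0.0837), that of Atg12 without wild-type 22 or 23 or Pink1-/- 18 or 25 (up to 0.0782), and that of Rpl23a without wild-type 20, 22 or 23 or Pink1-/- 25 (up to 0.0703). Those of Penk (without wild-type 20, 22 or 23 or Pink1-/- 18 or 25, up to 0.118), Gpr17 (wild-type 22, 23 or 24 or Pink1-/- 18 or 25, 0.0602) and C3 (wild-type 20, 22 or 24 or Pink1-/- 18 or 19, 0.101) each depended on 5 libraries. Tf (all but wild-type 23 and Pink1-/- 17, up to 0.0888) and Ndufa6 (all but Pink1-/- 17 and 25, 0.0826) depended on 6. Ndufb7 (all but Pink1-/- 19, up to 0.118), Aspa (all but Pink1-/- 17, 0.122), Aaas (all but Pink1-/- 19, 0.110), Rps10 (all but wild-type 22, 0.118) and Pdgfrb (all but wild-type 20, 0.0648) depended on 7.

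The female comparison asks the same question in females, and far fewer genes passed. Female Pink1-/- brains had 4 genes that rose and 5 that fell out of 15265 tested. The zinc finger gene Zfp40 and the signalling scaffold Cnksr3 rose, as did the unnamed loci LOC100360573 and LOC100361025. Besides Pink1, the falls were in Slc35c2, a sugar-nucleotide transporter family member of the secretory pathway, Akr1b8, an aldo-keto reductase, Srd5a1, the type 1 steroid 5-alpha-reductase, and Golgb1, the Golgi tether giantin.

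Slc35c2 fell from 26.2 ± 3.17 to 8.53 ± 1.12 CPM (n = 4 per group), a log2 fold change of -1.61 (SE 0.12, edgeR adjusted p = 0.00022). Akr1b8 fell from 46.7 ± 1.94 to 18.7 ± 2.18 CPM (-1.32, edgeR adjusted p = 0.00013) and Srd5a1 from 25.0 ± 2.65 to 12 ± 0.761 CPM (-1.05, edgeR adjusted p = 0.0014). Golgb1 fell from 321 ± 16.8 to 217 ± 13.7 CPM (-0.57, edgeR adjusted p = 0.0127). Zfp40 rose from 26.9 ± 2.82 to 49.1 ± 4.26 CPM (0.87, edgeR adjusted p = 0.0063) and Cnksr3 from 17.0 ± 1.44 to 28.9 ± 3.03 CPM (0.76, edgeR adjusted p = 0.0196). LOC100360573, chosen after its values were seen because few genes passed, went from 0.344 ± 0.108 to 4.55 ± 0.665 CPM (log2 fold change 3.68). Next by p and not past the threshold were Cep295 (0.82, edgeR adjusted p = 0.172), Arpc5 (0.40, 0.236) and Olr1747-ps (2.02, 0.236) on the higher side and the autophagy regulator Nrbf2 (-0.74, 0.0603) on the lower side.

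In all 9 female calls the groups did not overlap. Over all genes tested this held for 3.38%, against 2.86% by chance, and 708 genes (4.64%) had an unadjusted p under 0.05. The common biological coefficient of variation was 0.160. Cnksr3 lost its call without wild-type 64 or 111 or Pink1-/- 548 or 736 (edgeR adjusted p 0.0835 to 0.101), and Golgb1 without wild-type 111 or Pink1-/- 548, 736 or 983 (0.0501 to 0.0927) and with library totals as scaling (0.113). The count was 16 without wild-type 980, and other tools called more genes, 58 with DESeq2 and 24 with limma-voom.

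Whether gene lists were called in females depended on the test. By camera at its preset correlation, 17 of 35 lists were called, 13 lower and 4 higher in Pink1-/- females. With an estimated correlation 0 lists were called (smallest adjusted p = 0.163, 3 lists with an unadjusted p under 0.05), and with fry also 0 (smallest adjusted p = 0.13, 3 unadjusted). Pink1 was the only list member called over all genes tested, and in 8 lists at least 1 member passed when adjusted over the list alone.

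The mitochondrially encoded genes had the smallest p of the female lists by camera at its preset correlation, whereas the mitophagy list had it with an estimated correlation and with fry. All 13 had a negative log2 fold change, with a median of -0.50 (camera adjusted p = 4.8e-22, but adjusted p = 0.366 with an estimated correlation). None fell over all genes tested (0 of 13), and 12 of 13 fell when adjusted over the list alone. Mt-nd1 stood at 2707 ± 143 CPM in wild type and 1754 ± 505 CPM in Pink1-/- (-0.63, edgeR adjusted p = 0.682), and Mt-nd5 at -0.50 (0.700). The 13 genes took 4.84% ± 0.316 of counts in wild-type and 3.86% ± 0.404 in Pink1-/- females (exact permutation p = 0.0286, the smallest possible). Pink1-/- 548 had the smallest share, 3.42%, and also only 1.77% of its counts at the 2 mitochondrial clone loci.

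**Figure D3:**
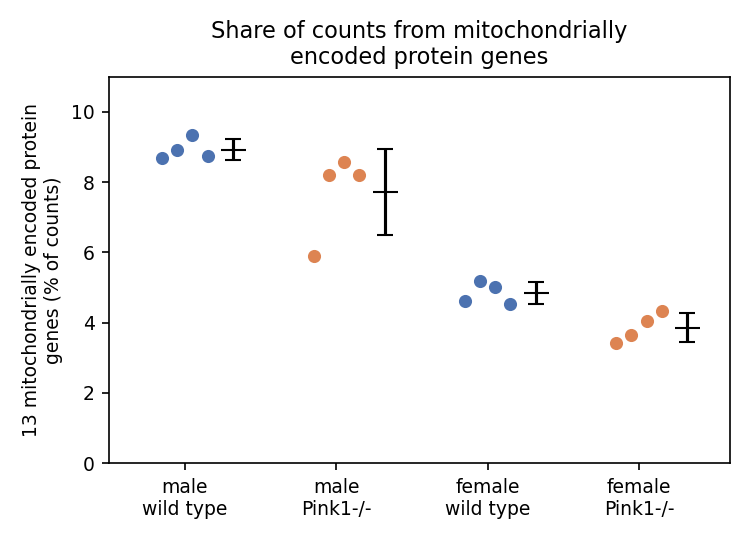
Share of all counts, in percent, from the 13 mitochondrially encoded protein genes in each library of the 4 groups; points are libraries and black bars the mean ± SD (n = 4). The share averaged 8.93% in wild-type and 7.72% in Pink1-/- males, and 4.84% in wild-type and 3.86% in Pink1-/- females; male Pink1-/- 17 is the low point at 5.89%.

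Nuclear genes for respiration mostly had negative log2 fold changes in females, and their lists were called only by camera at its preset correlation. Of 35 complex I genes 32 had a negative log2 fold change (median -0.09; camera adjusted p = 0.00015, adjusted p = 0.598 with an estimated correlation), with Ndufa1 at -0.25 and Ndufa10 at -0.20. Of 39 genes of complexes II to V, 37 did (median -0.12; camera adjusted p = 4.2e-07, adjusted p = 0.598 with an estimated correlation), with Cox8a at -0.28 and Uqcrfs1 at -0.16. For the tricarboxylic acid cycle it was 19 of 22 (Dlat -0.15, Pdhb -0.18; camera adjusted p = 0.0017) and for glycolysis 16 of 19 (Tpi1 -0.42, Pgam1 -0.13; camera adjusted p = 0.0050), each with adjusted p = 0.598 with an estimated correlation. In these 4 lists 0 members passed over all genes tested, and adjusted over the list alone Tpi1 was the only one, 1 fall in glycolysis.

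Lists for protein and organelle turnover were also called lower in Pink1-/- females only by camera at its preset correlation. In the mitophagy list 23 of 30 genes had a negative log2 fold change (camera adjusted p = 4.6e-06, adjusted p = 0.163 with an estimated correlation). Without Pink1 it was 22 of 29, with a mean log2 fold change of -0.06 instead of -0.20 and a camera adjusted p of 0.0232 (adjusted p = 0.537 with an estimated correlation). Pink1 was the 1 fall under either adjustment, with Optn at -0.20 and Fundc1 at -0.29. In the proteasome list it was 37 of 40 (camera adjusted p = 3.4e-05, adjusted p = 0.613 with an estimated correlation), with Psma4 at -0.22, and 1 member fell when adjusted over the list alone. Autophagy and lysosome genes (23 of 35 negative; Grn -0.33, Atg12 -0.26) had a camera adjusted p of 0.0400, which was 0.190 with library totals as scaling and adjusted p = 0.636 with an estimated correlation. Heat shock genes (13 of 17 negative; Fkbp4 -0.16, Hspa4l -0.13) had a camera adjusted p of 0.0279 and adjusted p = 0.645 with an estimated correlation. No gene of the latter pair of lists passed under either adjustment (0).

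Of the neuronal lists in females, 3 were called lower, only by camera at its preset correlation. Catecholamine genes had 12 of 13 negative values, with the rate-limiting enzyme gene Th at -1.97 (-2.33 to -0.49 over alternatives) and Ddc at -0.60 (camera adjusted p = 4.7e-05, adjusted p = 0.598 with an estimated correlation). Cholinergic motor neuron genes had 20 of 23 (Chodl -1.88, and -0.16 without wild-type 504; camera adjusted p = 0.0395, adjusted p = 0.764 with an estimated correlation). Synaptic vesicle genes had 25 of 28 (Syn2 -0.23, Vamp1 -0.26; camera adjusted p = 0.0055, adjusted p = 0.598 with an estimated correlation). None of these genes passed under either adjustment (0). The wild-type level of Th rested on wild-type 504 and 980 (22.7 and 12.4 CPM), while the other female libraries of both genotypes had 1.24 to 3.28 CPM. Motor neuron content differed between libraries of the same genotype: the acetylcholine-synthesising enzyme gene Chat ran from 6.22 CPM in wild-type 111 to 77.1 CPM in wild-type 504, and stood at 13 CPM in Pink1-/- 602.

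Of the lists for glia, vessels, meninges, blood and immune function, camera at its preset correlation alone called 4 higher in female Pink1-/- brains and antigen presentation lower. Astrocyte genes had 12 of 18 positive values (Gja1 0.33, the 1 rise adjusted over the list alone, and Aldh1l1 0.18; camera adjusted p = 0.0279, adjusted p = 0.645 with an estimated correlation). Vascular genes had 13 of 20 (Pdgfrb 0.35, but Emcn -0.42; camera adjusted p = 0.0279, adjusted p = 0.610 with an estimated correlation). Meninges genes had 11 of 16 (Ptgds 0.23, Lum 0.71; camera adjusted p = 0.0400, which was 0.0884 with library totals as scaling, and adjusted p = 0.610 with an estimated correlation). The 3 blood genes were positive (Alas2 1.70, the 1 rise adjusted over the list alone, and Hbb 0.86; camera adjusted p = 0.0279, adjusted p = 0.598 with an estimated correlation). Both values rested largely on Pink1-/- 983, with 157 CPM of Hbb against 24.6 to 35.7 CPM in the other Pink1-/- females and 4.94 CPM of Alas2 against 0.988 to 1.17 CPM; without it Alas2 stood at 0.76 and Hbb at -0.18. Antigen presentation had 13 of 20 negative values (RT1-S3 -0.77, but RT1-T24-1 1.02), with 1 rise and 3 falls adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.425 with an estimated correlation).

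The other 18 lists were not called in females. Among their members with small p were Gch1 (-0.99) and Vps13c (0.22) for familial parkinsonism, Htr2a (-1.0) and Tph2 (-1.5) for serotonin, Gad2 (-0.36) and Gad1 (-0.32) for inhibition, Slc17a6 (0.15) and Gria3 (-0.11) for glutamate, and Cck (-1.74) and Nts (1.10) for neuropeptides. For glia and other tissue they were Tmem119 (-0.60) and Cd53 (0.35) for microglia, Mobp (0.26) and Tf (-0.40) for myelin, Cspg4 (0.27) and Tmem100 (0.22) for precursors, Kcne2 (0.44) and Slc4a5 (-0.27) for choroid plexus, and Car8 (-0.42) and Cbln3 (-0.78) for cerebellum. For position they were Hoxb5 (-1.36) and Hoxb2 (0.52) for the Hox genes and Ppp1r1b (0.15) for the forebrain. For defence and stress they were Tnfaip3 (0.44) and Tlr2 (-0.51) for inflammation, Stat2 (-0.39) and XAF1 (0.72) for interferon, Gstm1 (0.19) and Prdx5 (-0.17) for antioxidants, Hspe1 (-0.33) and Hspd1 (-0.16) for the stress response, Homer1 (0.21) and Nr4a3 (-0.89) for immediate early genes, and Rpl13 (0.12) and Rpl28 (-0.23) for the ribosome. In 6 of these lists (microglia, choroid plexus, cerebellum, inflammation, interferon and ribosome) the median, the mean and the test differed in sign, and Stat2 was the 1 member of these lists to fall when adjusted over the list alone.

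None of the 17 female lists called by camera at its preset correlation was called with an estimated correlation or with fry. By camera at its preset correlation, 7 were called whichever library was left out. These were the lists of mitophagy, both respiratory sets, the mitochondrially encoded genes, the tricarboxylic acid cycle, catecholamines and antigen presentation. Taken without Pink1, the mitophagy list lost its call when wild-type 504 was left out (camera adjusted p = 0.152). The widest losses among the other 10 came without wild-type 504 (camera adjusted p = 0.884 for motor neurons, whose direction turned, 0.743 for heat shock, 0.607 for autophagy, 0.525 for meninges and 0.177 for the proteasome), without wild-type 111 (0.789 for astrocytes), without wild-type 980 (0.247 for vascular genes and 0.118 for glycolysis), without Pink1-/- 983 (0.599 for blood, whose direction also turned) and without Pink1-/- 548 (0.135 for synaptic vesicles).

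The series compares the genotypes in both sexes, which raises the question of which changes they share. Pink1, Akr1b8 and the unnamed locus LOC100361025 were called in males and females in the same direction, and 0 genes in opposite directions; the count was 5 without male Pink1-/- 19 or female wild-type 980. Akr1b8 fell in males from 13.7 ± 1.65 to 6.67 ± 1.41 CPM (n = 4 per group), a log2 fold change of -1.05 against -1.32 in females. LOC100361025 rose in males from 0.174 ± 0.109 to 4.47 ± 1.27 CPM (4.58) and in females from 1.09 ± 0.307 to 6.27 ± 0.849 CPM (2.52). Independent lists would share 0.0327 higher and 0.0615 lower genes, against 1 and 2 observed (Fisher's exact test, 1-sided p = 0.0323 and 0.0015). Pink1 defines the groups, and without it 1 lower gene was shared against 0.0489 (Fisher's exact test, 1-sided p = 0.0480).

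In all, 314 male calls other than Pink1 were tested in females, and 215 (68.5%) had the same sign there. Of these, 52 also had an unadjusted p under 0.05 in females. Their median absolute log2 fold change was 0.61 in males, and the median female value in the male direction was 0.08. Of the 20 largest male changes, 9 had the same sign and an unadjusted p under 0.05 in females, among them Slc39a12 (-0.95), Cd4 (-1.31), Eqtn (1.18) and Olr1747-ps (2.02). Across 13585 genes, which are not independent replicates, the log2 fold changes of both sexes had a Pearson correlation of 0.20 and a Spearman correlation of 0.17.

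The test of the difference between sexes covered 15042 genes, and 12 passed, 6 with a higher and 6 with a lower effect in females. Slc7a5, the large neutral amino acid transporter, rose in males (log2 fold change 0.61, edgeR adjusted p = 0.0054) and stood at -0.18 in females, a female minus male difference of -0.79 (SE 0.12, edgeR adjusted p = 0.0165). Slc35c2 fell in females alone (-1.61 against -0.03 in males, difference -1.58, edgeR adjusted p = 0.0225), as did Golgb1 (-0.57 against 0.06, difference -0.62, 0.0419). The nuclear pore gene Aaas rose in males (0.70 against -0.30, difference -0.99, 0.0499). The peptide transporter Slc15a2 (-0.43 against 0.25, difference 0.68) and Heca (-0.45 against 0.05, difference 0.51) fell in males, both with an edgeR adjusted p of 0.0499 for the difference. The other 6 were loci without a symbol, of which the extremes are named after their values were seen, with differences from -5.89 for LOC257642 to 4.01 for AABR07001512.1. Scaling by library totals gave 3 calls and DESeq2 122. Leaving out 1 library gave 3 to 13: 3 without male wild-type 22 or female Pink1-/- 736, 4 without male Pink1-/- 25, 5 without male wild-type 20, male Pink1-/- 17 or female Pink1-/- 983, 6 without male Pink1-/- 18, and 7 without female wild-type 64 or 980 or female Pink1-/- 602. Each of the 6 named genes lost its call without at least 1 library, Heca with any library left out (edgeR adjusted p up to 0.129), and all 6 lost it with library totals as scaling.

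The authors' deposited tables list 859 male genes at a false discovery rate under 0.05, 513 higher and 346 lower in Pink1-/-, and 62 female genes, 34 higher and 28 lower. The authors' deposited table held 316 of the 317 male genes called here and all 9 of the female ones. Log2 fold changes in the authors' deposited tables and in the quasi-likelihood fits had Pearson correlations of 0.9999 across genes, which are not independent replicates, in males and in females. The likelihood ratio test of edgeR run here called 957 and 49 genes.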

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

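The tests chosen only after the results were seen are those of a shared effect missed in females, of a single library in males and in females, of differences that act alike in both sexes, and of reads shared between copies.

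Genes of the blood, of catecholamine neurons and of mitochondria stood out in single libraries. In each group of 4, a library was taken as far from the others when its gap to the nearest one as a share of the group's range passed Dixon's 95% limit, which chance gives in about 1 of 20 groups. This held in 18 of 248 groups, against 12.4 by chance, so single cases carry little weight. Female Pink1-/- 983 had 157 CPM of the beta-globin gene Hbb against 24.6 to 35.7 CPM in the other Pink1-/- females, and 4.94 CPM of the erythroid haem enzyme gene Alas2 against 0.988 to 1.17 CPM. Its blood score, a mean of centred log2 levels, was 2.10 against -0.372 to -0.112. The same library had 117 CPM of Optn and 46.8 CPM of Heca. Female Pink1-/- 602 had a catecholamine score of -0.744 against -0.104 to 0.0168, and 237 CPM of Golgb1 against 209 to 210 CPM. Female wild-type 504 had 35.4 CPM of Fundc1.

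In males, Pink1-/- 17 had the smallest share of mitochondrially encoded transcripts in its group (5.89% against 8.21% to 8.57%) and the largest share of 7SL RNA (4.28% against 1.16% to 1.45%). It also had 2.86 CPM of Pyroxd2, 25.5 CPM of Aspa and 32.8 CPM of Atg12. Wild-type 23 had a 7SL share of 0.282% against 1.12% to 1.24%. Pink1-/- 19 had 4.44 CPM of Ogn and Pink1-/- 25 had 1.88 CPM of Olr1747-ps. Total counts were low in male Pink1-/- 19, rounded to 10959400, and in female Pink1-/- 602, rounded to 13875600.

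The genotype effect differed between the sexes in 12 genes by the interaction test. The female minus male differences in log2 fold change were -0.79 for Slc7a5, -1.58 for Slc35c2, -0.62 for Golgb1, -0.99 for Aaas, 0.68 for Slc15a2 and 0.51 for Heca. For loci without a symbol they were 4.01 (AABR07001512.1), 3.83 (LOC689899), 1.20 (LOC100362027), 0.93 (LOC102552284), -2.31 (LOC100911515) and -5.89 (LOC257642). The last rests on few libraries, since its male Pink1-/- level was 296 ± 379 CPM. Of 100 draws of regrouped libraries 2 gave as many interaction genes, the real one with 12 included, and the highest other gave 164. So high a count was rare among the draws, but this does not decide whether the effects differ between the sexes. Regrouping breaks up the genotype effect within each sex, so the draws do not stand for equal effects in both. A draw with so many calls also points to a structure among the libraries other than genotype.

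Many more genes were called in males (317) than in females (9). For males 1 of 35 splits of the libraries, the real one, gave as many genes, and the highest other gave 2. This makes chance an unlikely source of the male count but does not exclude it, since 35 splits cannot give a smaller share. The other splits mix the genotypes on each side, which lowers their counts where genotype has an effect. For females 2 of 35 splits gave at least 9 genes, so chance cannot be excluded for that count. The highest other gave 182, with wild-type 64 and 504 and Pink1-/- 548 and 736 on one side. This points to a structure of the female libraries unrelated to genotype. Those libraries also had the most Chat (40.8 to 77.1 CPM, against 6.22 to 33.7 CPM in the other females). Their Hox scores were the lowest (-2.34 to 0.0794 against 0.574 to 1.51), while motor neuron scores overlapped (0.0855 to 0.989 against -1.28 to 0.211). Dissection level or motor neuron content is thus a candidate for this structure, picked after the values were seen and not tested. For the 3 genes called in both sexes, 1 of 100 draws, the real one, gave as many and the highest other gave 0. This count says little, since other male splits called at most 2 genes and Pink1 defines the groups.

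Several tests address the excess of male calls. Genes picked in part of the male libraries had a median female effect of 0.173 times their effect in the held-out male libraries (0.0693 to 0.411 over 36 halvings), which argues against equal effects missed in females. Leaving out wild-type 22 gave the lowest male count, 98, so no single male library accounts for the excess. With the 7SL share as a covariate, the called male genes kept a median of 0.863 of their effect (0.851 to 0.891, from resampling genes, not libraries). The number of calls fell from 317 to 92. The effects thus mostly kept their size, but part of the count may still depend on that measure of library quality. Sex and processing run cannot be told apart, so a difference between the sexes and a difference between the runs both stay open. Dissection level was not separated from them either. The Hox list, with 11 tested members in females, had under 3 in males and could not be tested there.

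Male calls lay next to each other more often than random genes. There were 20 pairs of neighbouring called genes, such as Mrc1 with Slc39a12 and Lacc1 with Ccdc122, against a mean of 6.25 in random draws (2 to 11 in 95%, permutation p = 1e-04, the smallest the draws can give), and 15 moved in one direction. Chromosome segments that differ between the rat lines are a candidate explanation, since only 1 of 35 splits, the real one, had as many pairs (highest other 14), which argues against neighbours that vary together in any grouping. Around Pink1 itself 2 of 200 tested genes were called (1%, upper bound 3.57%), against 2.28% elsewhere (Fisher's exact p = 0.334). This argues against segments carried along with that locus as the source of the pattern. A short segment beside Pink1 is not excluded, since the called genes, Pqlc2 and Padi2, lay 11 and 22 genes from it on the same side. Male calls over 2-fold had a female effect 0.314 times as large (0.195 to 0.392), a ratio that decides nothing because these genes were picked on the male values it is taken over, and 64 of 75 (85.3%) had the same sign in females. Genes picked in part of the male libraries with over 2-fold change there (60 to 161 genes) had a median female effect of 0.243 times their effect in the held-out male libraries (0.171 to 0.436 over 36 halvings), which argues against differences that act alike in both sexes as the whole of the pattern. Names typical of copied loci had an odds ratio of 1.16 among male calls (0.812 to 1.61), which leaves shared reads open, and of 4.05 among calls over 2-fold (2.43 to 6.60, 27 of 78). The 5 identifiers with identical counts are among these 27, so 1 distinct row was counted 5 times in both odds ratios. The calls were not matched to the other genes for expression level.

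Mitochondrially encoded transcripts took a smaller share of counts in Pink1-/- libraries of both sexes, but their mean score in males did not separate the genotypes (exact permutation p = 0.229). In males the difference of that score went from -0.22 to -0.03 without Pink1-/- 17, a ratio of 0.158, so in males it rests mostly on that library. In females it went from -0.50 to -0.33 without Pink1-/- 548, a ratio of 0.665, so that library alone does not carry it. With the motor neuron score as a covariate the female median kept 0.985 of its size (0.946 to 0.986, from resampling transcripts, not libraries). The 13 transcripts vary together (estimated correlation 0.889), so that interval does not measure the spread between animals. The small change argues against motor neuron content, as measured by those genes, as the main source. Position as measured by the Hox genes was not used as a covariate. Removing the ribosomal and 7SL loci moved nothing (ratio 1.0) and decides nothing. RNA handling, dissection position and a genotype effect on mitochondrial transcripts may each contribute and were not separated.

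The gene lists add no firm evidence. In females 13 of 35 splits called at least as many lists as the real 17, with 22 as the highest other, so chance cannot be excluded for the list count. In males all 35 of 35 splits called at least the real 0 lists, with 12 as the highest other, which a real count of 0 makes certain and which says nothing about chance; camera gave 4 lists an unadjusted p under 0.05, and estimated correlation and fry also called 0.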

How the results depend on the processing

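Alternatives added only after the data were seen left out male Pink1-/- 17 with wild-type 23, left out female wild-type 111 with Pink1-/- 602, adjusted for the motor neuron score, removed the ribosomal and 7SL loci, or took Pink1 out of the lists (female lists stayed at 17, male at 0). Pink1 was called in both sexes under each alternative, with log2 fold changes from -5.33 to -5.10 in males and -4.51 to -4.00 in females when 1 library was left out. Of 43 named male calls, all held with RLE size factors, limma-voom and the likelihood ratio test, 30 with library totals and 18 with 1 surrogate variable. Of 8 named female calls, 7 held with library totals and 5 without wild-type 111 and Pink1-/- 602.

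The male count of 317 was 1219 at an adjusted p under 0.10, 168 with library totals (162 shared), 523 without a filter, 853 with DESeq2, 957 with the likelihood ratio test, 61 with 1 surrogate variable (58 shared), 609 with all 16 libraries in 1 fit, 153 without Pink1-/- 17 and wild-type 23 (fewer libraries), and 98 (without wild-type 22) to 217 (without Pink1-/- 19) with 1 library left out. The female count of 9 was 58 with DESeq2, 49 with the likelihood ratio test, 24 with limma-voom, 17 with all 16 libraries, and 7 to 16 with 1 library left out (16 without wild-type 980). The 12 interaction genes became 29 at 0.10, 3 with library totals, 19 without a filter, 21 at a mean of 1 CPM, 122 with DESeq2, 95 with the likelihood ratio test, 27 with limma-voom, 4 with 1 surrogate variable, and 3 to 13 with 1 library left out. The 3 genes called in both sexes became 5 at 0.10 and without a filter, 16 with DESeq2, 18 with the likelihood ratio test, 11 with limma-voom, and 3 to 5 with 1 library left out. With 1 surrogate variable 2 were left, as Akr1b8 lost its male call (edgeR adjusted p = 0.0653). Male lists went from 0 to 3 without a filter, and to 0 to 2 with 1 library left out. The 17 female lists became 0 with an estimated correlation and 0 with fry (3 unadjusted each), and 12 to 19 with 1 library left out. The authors' deposited male table held 1603 genes under 0.10 instead of 859. A looser threshold admits more genes by construction, and leaving out libraries leaves fewer samples; elsewhere the cause was not tested. The direction of 2 called female lists turned, with the call lost: motor neuron genes without wild-type 504 (camera adjusted p = 0.884) and with the motor neuron score as a covariate, an alternative added after the data were seen (0.979), and blood genes without Pink1-/- 983 (0.599). That covariate is built from the motor neuron genes themselves, so the loss of their call with it was to be foreseen and says nothing. Directions also reversed for single genes that had not passed: Slc35c2 in males, near 0, stood at 0.04, 0.02, 0.04 and 0.11 without wild-type 20, wild-type 24, Pink1-/- 18 and Pink1-/- 19 (-0.23 to 0.11 over all omissions), and Hbb in females at -0.18 without Pink1-/- 983, its library with most blood transcripts (-0.18 to 1.13 over all omissions). Small effects were mostly missed in simulated data, where 4% of male and 2% of female genes with the smallest simulated change were called; depth was not varied. No paired analysis was possible because the groups share no animal numbers. The prior count of 2 added for log2 CPM values was not varied.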

Other observations

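No test in this part was run beyond the planned tables, and the values were chosen after they were seen.

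Transcripts of motor neurons, which mark how much of the nucleus ambiguus or of other motor nuclei a sample holds, varied widely between libraries of the same sex. The acetylcholine synthesis gene Chat ran from 6.22 CPM in female wild-type 111 to 77.1 CPM in female wild-type 504, a 12.4-fold range, and from 6.77 CPM in male Pink1-/- 18 to 27.1 CPM in male wild-type 23. The vesicular acetylcholine transporter gene Slc18a3 ran from 1.23 to 27.4 CPM and the motor neuron factor gene Isl1 from 0.107 to 4.60 CPM over the same pair of female libraries.

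Genes with positional expression also differed between female libraries. Hoxb5, a gene of the caudal hindbrain and spinal cord, had 7.35 CPM in female wild-type 111 and no count in female Pink1-/- 548. Within males it ran from 0 to 0.169 CPM. The catecholamine enzyme gene Th ran from 1.24 CPM in female Pink1-/- 602 to 22.8 CPM in female wild-type 504.

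Several male calls lacked a gene symbol, and some of them had similar values in females without being called there. AABR07021734.2 had a log2 fold change of 4.07 in males and 3.54 in females, and AABR07000733.1 had 2.85 and 2.83. AABR07000398.1 had 4.67 in males (18.4 to 465 CPM) and 0.07 in females. Its male value was imprecise (SE 1.06) and only just passed (edgeR adjusted p = 0.0452).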
